A study of Mus musculus with 12 samples.

How the data were processed

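RNA-seq was done on 12 single whole mouse embryos of a mixed C57BL/6 x 129Sv background, with poly-A selection and paired reads of 50 bases, per the labels. The table used here holds the authors' deposited raw counts per gene symbol, 23284 genes in 12 columns, 1 column per embryo. Per the submitters' processing notes, FastQC, STAR, featureCounts and DESeq2 were used with genome build mm9. Versions, annotation, strand setting and the treatment of reads that map to several places are not given in the sources used here. Counts of genes with near-identical copies or overlapping neighbours are therefore uncertain. Total counts ranged from 16802367 to 21346245 per embryo. Intervals given on counts cover counting error only.

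Samples were grouped by the genotype in the labels, 4 wild type and 8 described as null for Tgif1 and Tgif2. Replicate numbers follow the order of the samples and pair nothing. The series text says that single embryos were used, so p-values measure the spread between embryos; shared litters are not excluded. Pairs of libraries within a group were compared by a chi-square per degree of freedom over genes with a pooled count of at least 20. The lowest value was 3.89, so no pair was within sampling noise.

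Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group, robust dispersions, and the quasi-likelihood F test of genotype with no covariate. Adjusted p is by Benjamini-Hochberg over the 14412 genes tested, with a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of F. CPM is the count scaled to a fixed library total after TMM scaling. Gene lists, 42 in all, were fixed before the data were examined and tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, for lists with at least 5 tested members, with Benjamini-Hochberg over lists. Camera with an estimated correlation and fry were run as alternatives. The genes named are Tgif1, Tgif2 and Evi5l; the 12 highest and 12 lowest log2 fold changes among genes past 0.05 with a mean of at least 1 CPM in a group and all 8 mutant-labelled embryos on one side of the wild-type mean, leaving out Xist, Y-linked and predicted genes; and up to 4 members with the lowest p from each list described. Some genes that this rule names are not reported here. Posterior, globin and paired-level genes named with single embryos were chosen after their values were seen.

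The test was tried on simulated counts with the means and library sizes of these 14412 genes. It recovered 47 of 62 genes changed by 1.5-fold, 62 of 70 changed by 2-fold and 63 of 68 changed by 4-fold, and 7 of 179 genes called were unchanged. Few genes were changed there, rises and falls had equal chance, and both groups had the same dispersions. This does not test data in which 51.5% of genes were called and spread differed between the groups. The list test called the 1 raised list and 0 of 36 lists with no raised member; genes were drawn independently there, so this does not test correlated lists.

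Alternatives fixed before the data were examined were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom with and without sample quality weights, other count filters, dispersions without robust estimation, each embryo left out in turn, Xist, red cell or yolk sac scores as covariates, the 50 most abundant genes left out, genes within 10 Mb of Tgif1 and Tgif2 left out, a test against 1.2-fold, and other thresholds. After seeing the data, removal of a trend on GC content and transcript length and the omission of mutant-labelled embryo 2, low in posterior and globin genes, with wild-type embryo 1, the wild-type embryo with the lowest yolk sac score, were added. Symbols were matched to the GRCm38.p6 RefSeq table, 20683 directly, 2355 through a unique synonym and 246 not at all. It served for names and neighbours, and for the distance window, whose limits in mm9 differ slightly. A near-identical copy is a GENCODE M21 transcript of another, non-overlapping gene with at least 200 bases at 95% identity or more by BLAST 2.17.0.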

Results

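RNA was measured in single whole mouse embryos at 9.0 days after fertilization, at about 9 to 10 somites, by sequencing of polyadenylated RNA. The labels place 4 embryos in a wild-type group and 8, with CDKO in their sample titles, in a group described as null for Tgif1 and Tgif2. These genes encode related homeodomain proteins that repress transcription and restrain TGF-beta and Nodal signalling, and TGIF1 is a human holoprosencephaly gene. The libraries held 17296017 to 20080786 counts in the wild-type group and 16802367 to 21346245 counts in the other. The series asks which genes change in early embryos that lack both genes. The labels give no litter, dissection date or library batch.

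Tgif1 was measured at 60.9 ± 2.52 CPM (SD, n = 4) in wild-type embryos and at 6.2 ± 0.528 CPM (SD, n = 8) in the mutant-labelled embryos, a log2 fold change of -3.29 (SE 0.07, adjusted p = 1.95e-14). All 8 mutant-labelled embryos lay below every wild-type embryo. Tgif2 was not lower: it stood at 87.3 ± 1.17 CPM in wild type and 97.9 ± 11.8 CPM in the mutant-labelled embryos, a log2 fold change of 0.16 (SE 0.08, adjusted p = 0.0958). A count over a whole gene does not check a deletion that leaves part of the transcript, the deleted part is not given in the sources used here, and Tgif2 has 1 near-identical copy in the transcript set, so the genotype at Tgif2 rests on the labels and the embryos are called mutant-labelled throughout. Evi5l, which encodes a RabGAP, rose from 3.09 ± 0.433 CPM to 19.6 ± 1.37 CPM, a log2 fold change of 2.66 (SE 0.11, adjusted p = 7.57e-11), in 8 of 8 mutant-labelled embryos. It was chosen with outside knowledge of the study on these samples and is not independent evidence.

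**Figure D1:**
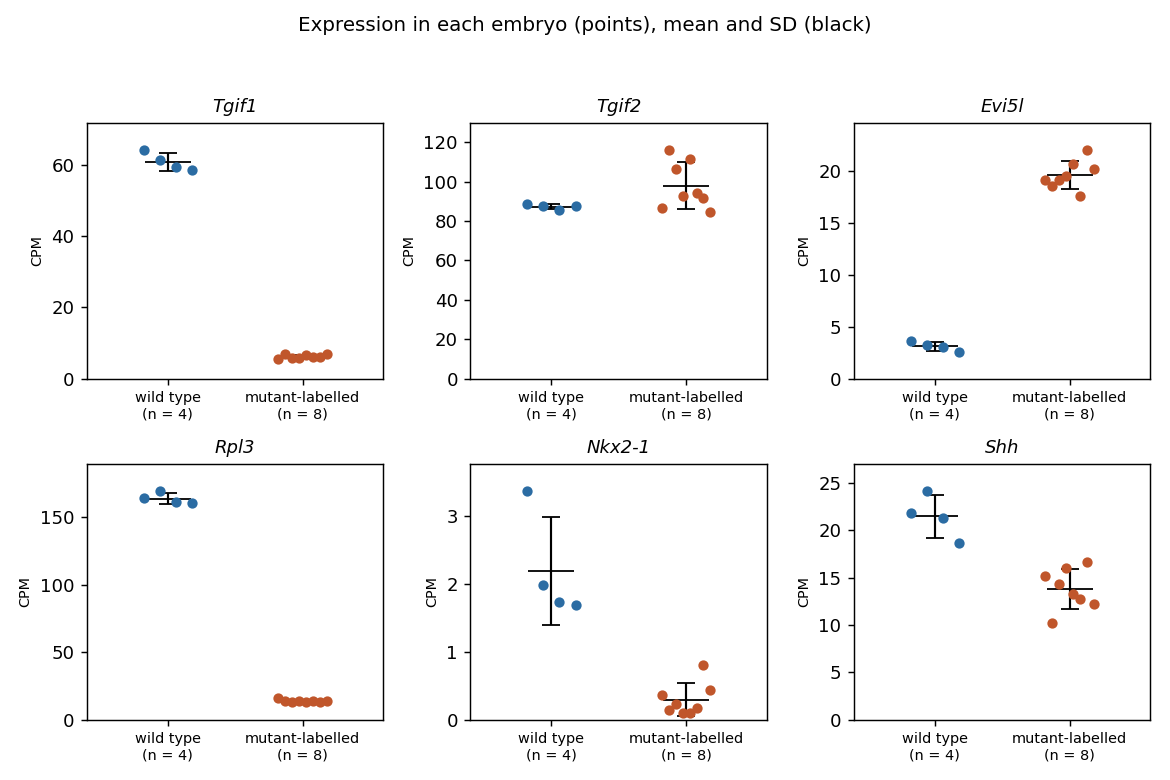
CPM of 6 genes in each of the 12 embryos, with the group mean and SD in black and wild-type embryos on the left of each panel. Tgif1, Rpl3, Nkx2-1 and Shh lie lower in all 8 mutant-labelled embryos than in any wild-type embryo, Evi5l lies higher, and the Tgif2 groups overlap.

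The mutant-labelled embryos differed from wild type in 7423 of 14412 genes tested (51.5%), of which 3840 were higher and 3583 lower. With the trends on GC content and transcript length removed the balance turned, to 3266 higher and 4507 lower. Most of the differences were small. The median absolute log2 fold change of the changed genes was 0.41, and 67.9% of them changed by less than 1.5-fold. Among larger changes rises outnumbered falls: 1712 genes rose and 670 fell by at least 1.5-fold, 726 rose and 201 fell by at least 2-fold, and 88 rose and 26 fell by at least 4-fold. In 4994 genes (34.7%) the groups did not overlap, against 0.404% of genes by chance. The first principal component, with 46.5% of the variance, separated the groups. Spread was wider among mutant-labelled embryos, with a biological coefficient of variation of 13.9% against 8.2% in wild type.

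Of the 12 genes with the highest log2 fold changes, all but Coro1a had a mean under 1 CPM over the wild-type embryos. Ankrd35 rose from 0.0773 to 2.59 CPM (log2 fold change 4.9, SE 0.35), and Dlgap1, a postsynaptic scaffold gene and the nearest protein-coding gene to Tgif1 on one side in the GRCm38.p6 gene table, rose from 0.88 to 15.6 CPM (4.13, SE 0.13). A pair of Rab GTPase genes followed, Rab9b (3.90, SE 0.49) and Rab40b (3.80, SE 0.28), and then the nuclear receptor gene Rorb (3.23, SE 0.25). The remaining genes of the 12 highest were Tagap (3.03), Ghrl, which encodes ghrelin (2.94), Ephx1 (2.90), Hsd3b6 (2.89), Coro1a (2.88), the stress-responsive gene Chac1 (2.87) and Ccdc109b (2.86), with adjusted p between 0.00237 and 1.68e-10. Coro1a was the most abundant of these, at 3.11 ± 0.271 CPM in wild type and 23 ± 2.91 CPM in the mutant-labelled embryos. Tagap has 2 near-identical copies, so its reads are uncertain.

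Among the largest falls, Rbm44 had 155 counts over the 4 wild-type libraries and 1 count over the 8 mutant-labelled libraries, a ratio of 316 (95% interval 55.9 to 12600, counting error only). Rpl3, a ribosomal protein gene, fell from 164 ± 4.07 to 14 ± 1.03 CPM (log2 fold change -3.55, SE 0.05). Rpl29, another ribosomal protein gene, fell by 3.66 on the log2 scale (SE 0.49), but wild-type embryo 2 stood at 5.01 CPM while the other wild-type embryos stood at 61.6 to 69.7 CPM, and its call was lost with sample quality weights (adjusted p = 0.0689). Ahcy, which encodes the enzyme that hydrolyses S-adenosylhomocysteine, had the same split, at 7.29 CPM in wild-type embryo 2 against 37.1 to 39.5 CPM in the others, with a log2 fold change of -2.59 (SE 0.32). Rpl29, Rpl3 and Ahcy have 35, 7 and 2 near-identical copies, so their counts are uncertain. Nkx2-1, a regulator of ventral forebrain and of lung and thyroid, fell from 2.19 ± 0.791 to 0.296 ± 0.243 CPM (-2.88, SE 0.39, adjusted p = 2.42e-05). Cer1, a secreted Nodal and BMP antagonist, fell by 2.43 (SE 0.44). The other genes of the 12 lowest were Tgif1, the meiotic recombinase gene Dmc1 (-2.90), Cbs (-2.64), Psma8 (-2.35), Fgfbp1 (-2.33) and Ankrd45 (-2.26).

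Ventral patterning and holoprosencephaly genes moved in both directions. For comparison, 51.5% of all 14412 genes tested changed, with 3840 higher and 3583 lower. Of 26 Sonic hedgehog pathway genes tested, 2 rose, 6 fell and 18 did not pass the test, with the same counts adjusted over the list alone. Shh itself fell from 21.5 ± 2.24 to 13.8 ± 2.15 CPM (log2 fold change -0.64, SE 0.12) and Gli1, a target of the pathway, by 0.40 (SE 0.09). Of 24 genes linked to holoprosencephaly, 5 rose and 9 fell, both over all genes and adjusted over the list alone, among them Zic2 (-0.51, SE 0.08), the BMP modulator gene Twsg1 (-0.55, SE 0.05) and the Nodal co-receptor gene Tdgf1 (-1.19, SE 0.22), which has 1 near-identical copy. Of 28 forebrain genes 3 rose and 9 fell, with the same counts adjusted over the list alone. Wild-type embryo 1 had a forebrain score (mean log2 CPM) of 3.65, against 3.13 to 3.2 in the other wild-type embryos. With it and mutant-labelled embryo 2 left out 4 forebrain genes rose and 4 fell, no Sonic hedgehog pathway gene rose and 4 fell, and 4 holoprosencephaly genes rose and 8 fell. None of these lists passed as a set by camera (adjusted p = 0.397, 0.188 and 0.318). By fry, which does not compare a list with other genes, the holoprosencephaly list passed (adjusted p = 0.00186). The Sonic hedgehog and forebrain lists did not (fry adjusted p = 0.1 and 0.181).

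More primary cilium genes fell than rose. Of 67 tested, 37 fell, 5 rose and 25 did not pass, with 37 and 5 adjusted over the list alone. Tctn2, a transition zone gene, fell from 36.7 ± 2.87 to 20.6 ± 2.15 CPM (log2 fold change -0.83, SE 0.08), the intraflagellar transport gene Ift74 by 0.71 (SE 0.08) and Rab23, a ciliary GTPase gene that restrains hedgehog signalling, by 0.66 (SE 0.05), each in 8 of 8 embryos. The list median was -0.22 (camera with a preset correlation, adjusted p = 0.000105; adjusted p = 0.799 with an estimated correlation).

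Presomitic, somite and Wnt genes fell more often than they rose. Of 32 presomitic and somite genes, 21 fell and 1 rose, with 22 and 1 adjusted over the list alone and a list median of -0.52 (adjusted p = 0.000985; adjusted p = 0.799 with an estimated correlation). Wnt3a, a posterior Wnt ligand gene, fell from 19.5 ± 1.29 to 11.4 ± 1.39 CPM (log2 fold change -0.78, SE 0.10), and Axin2, a feedback target of Wnt, by 0.41 (SE 0.06). Of 27 Wnt ligand and target genes 13 fell and 3 rose, also over the list alone, among them Wnt8a (-1.54, SE 0.27), with adjusted p = 0.0399 for the list (adjusted p = 0.799 with an estimated correlation). The Wnt call was lost without wild-type embryo 2 (adjusted p = 0.0515), wild-type embryo 4 (0.084), mutant-labelled embryo 7 (0.0585) or mutant-labelled embryo 8 (0.0582), and with DESeq2 (0.0934), sample quality weights (0.0759), a stricter count filter (0.0931) and the trends on GC content and length removed (0.0519). Mutant-labelled embryo 2 stood apart in posterior genes, with Cdx4 at 0.238 CPM against 19.6 to 46 CPM in the other mutant-labelled embryos and 64.1 to 87.8 CPM in wild type. Without it 21 presomitic and somite genes fell and 1 rose. Of 11 Hox genes of paralog groups 9 to 13, 1 fell and none rose with that embryo, and 5 fell and 1 rose without it. Hoxd13 was the gene that fell with it included (-2.02, SE 0.37).

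**Figure D2:**
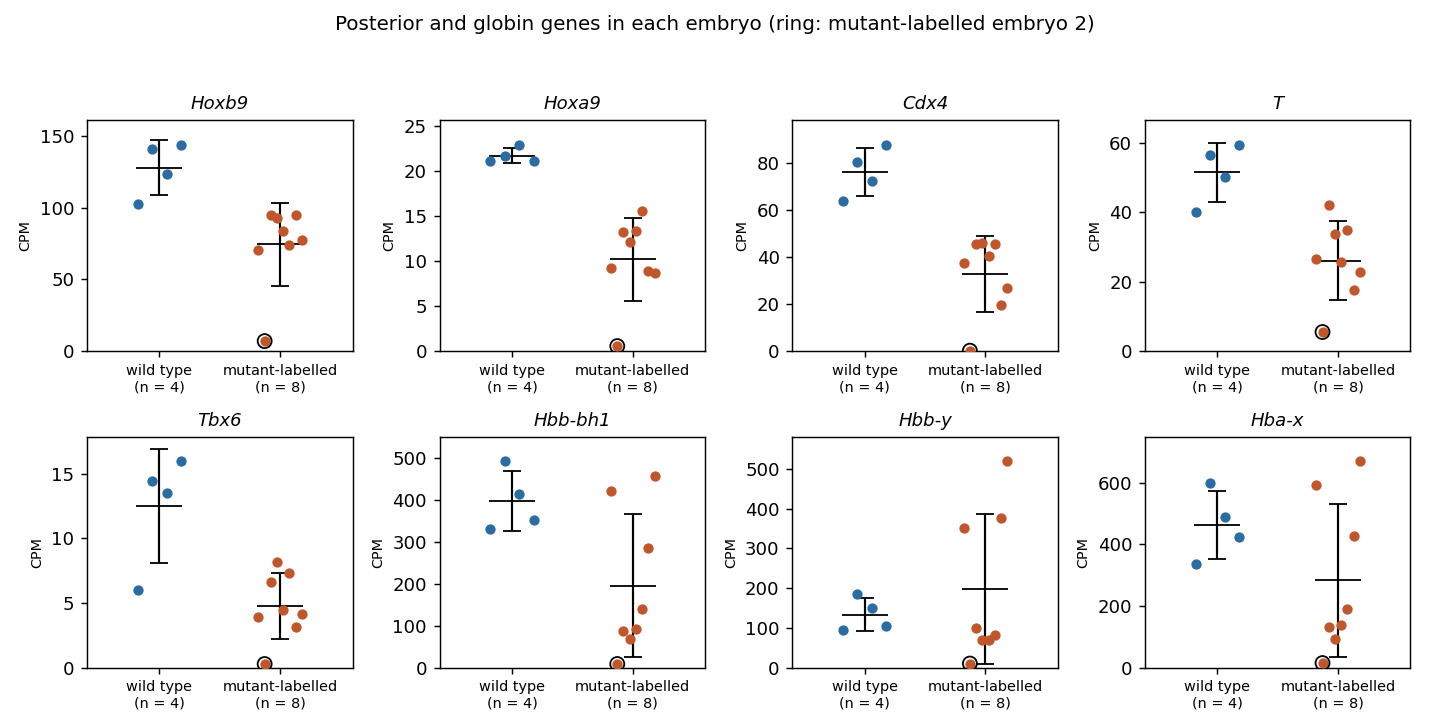
CPM of 5 posterior genes and 3 embryonic globin genes in each of the 12 embryos, with group mean and SD in black and mutant-labelled embryo 2 ringed. Embryo 2 is the lowest of the 12 in each panel, with Hoxb9 at 7.05 CPM against 70.7 to 95.1 CPM in the other mutant-labelled embryos, and the globin genes vary widely among those embryos.

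Most heart genes rose. Of 33 tested, 25 rose, none fell and 8 did not pass, and 26 rose adjusted over the list alone. Tnni1, a troponin gene, rose from 62.7 ± 5.36 to 183 ± 36.6 CPM (log2 fold change 1.55, SE 0.14), Wnt11 by 1.16 (SE 0.14) and the transcription factor gene Hand2 by 0.68 (SE 0.10), each in 8 of 8 embryos. The list median was 0.68 (adjusted p = 2.22e-05; adjusted p = 0.799 with an estimated correlation).

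Metabolic and stress genes also rose more often than they fell. Of 33 hypoxia and glycolysis genes 23 rose and none fell, also over the list alone, with the hexokinase gene Hk1 at 59.9 ± 2.39 CPM in wild type and 125 ± 20.2 CPM in the mutant-labelled embryos (log2 fold change 1.06, SE 0.11) and the phosphofructokinase gene Pfkp at 1.31 (SE 0.17). Of 24 cholesterol genes 11 rose and 1 fell, over all genes and over the list alone, with Pmvk at 1.26 (SE 0.08) and Lss at 0.97 (SE 0.14). Of 27 genes of the integrated stress and unfolded protein responses 16 rose and 4 fell, over all genes and over the list alone, with Herpud1 at 1.08 (SE 0.08). The adjusted p of these lists was 0.000105, 0.00669 and 0.022, and for each of them adjusted p = 0.799 with an estimated correlation. The stress list lost its call with blood content as a covariate (adjusted p = 0.108) and with the trends on GC content and length removed (0.0705). Of 26 immediate early and heat shock genes, which move with handling of tissue, 12 rose and 2 fell. That list did not pass by camera (adjusted p = 0.0724) and passed by fry, which does not compare a list with other genes (0.00499).

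**Figure D3:**
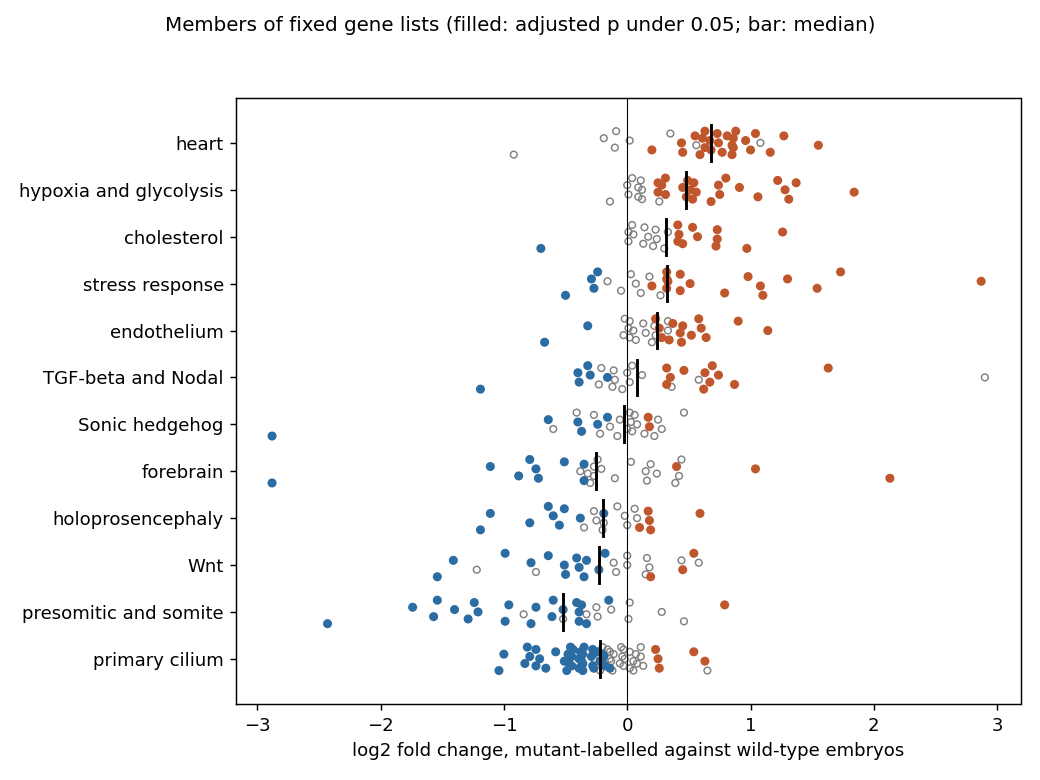
Log2 fold change of each tested member of 12 gene lists, mutant-labelled against wild-type embryos, with filled points for members at adjusted p under 0.05 and a bar at each list median. Heart members lie mostly to the right of 0, with a median of 0.68, and primary cilium members mostly to the left, with a median of -0.22.

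The TGF-beta and Nodal, retinoic acid and RabGAP lists had members in both directions and did not pass as sets by camera. Of 30 TGF-beta and Nodal genes 11 rose and 6 fell, with 12 and 6 adjusted over the list alone. Tgfbr2, a TGF-beta receptor gene, rose by 0.63 (SE 0.09) and Smad2 fell by 0.32 (SE 0.04). Of 32 retinoic acid genes 10 rose and 2 fell, also over the list alone, with the retinol transporter gene Stra6 at -0.64 (SE 0.12). Of 25 RabGAP genes, a list that holds Evi5l, 12 rose and 5 fell, with 12 and 6 adjusted over the list alone. The camera adjusted p of these lists was 0.495, 0.259 and 0.425. All passed by fry, which does not compare a list with other genes (adjusted p = 0.00927, 0.0354 and 0.0024).

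Some markers of other cell types differed too. Over all genes tested 51.5% changed, so a count near that share is not particular to a list. Of 30 endothelial genes 14 rose and 2 fell, also over the list alone, with the receptor genes Tek at 0.90 (SE 0.16) and Tie1 at 0.60 (SE 0.10). The endothelial call (adjusted p = 0.0399; adjusted p = 0.799 with an estimated correlation) was lost without wild-type embryo 1 (0.0647), wild-type embryo 4 (0.0899) or mutant-labelled embryo 6 (0.0878), and with DESeq2 (0.16), sample quality weights (0.072), a stricter count filter (0.0895) and the trends on GC content and length removed (0.101). Of 30 genes listed for trophoblast, parietal endoderm and decidua only 16 were tested. Of these 12 rose and none fell, also over the list alone (adjusted p = 0.00149, and 0.799 with an estimated correlation). Among them were the matrix gene Sparc (0.90, SE 0.09) and the muscle gene Des (0.94, SE 0.13), which embryonic mesoderm also expresses. Slco2a1 (1.51, SE 0.23) and Angpt2 (1.17, SE 0.21) rose too. These counts do not show more placental or decidual tissue. Of 23 allantois, amnion and lateral mesoderm genes 12 rose and none fell, also over the list alone, with Tbx5, a heart and forelimb regulator, at 1.0 (SE 0.16) (adjusted p = 0.00199; adjusted p = 0.799 with an estimated correlation). Of 22 primitive red cell genes 3 fell, 1 rose and 18 did not pass, with the same counts adjusted over the list alone. The list median was -0.70 (camera adjusted p = 0.0117, and 0.799 with an estimated correlation). The call was lost with DESeq2 (adjusted p = 0.384), fry (0.1), a stricter count filter (0.141) and the trends on GC content and length removed (0.0555). It was also lost with the score of the list itself as a covariate (0.86), which removes its difference by construction. Hbb-bh1, an embryonic globin gene, ranged from 9.05 CPM in mutant-labelled embryo 2 to 457 CPM among the mutant-labelled embryos, and from 332 to 493 CPM in wild type. Hbb-y, another embryonic globin gene, stood at 10.6 CPM in mutant-labelled embryo 2, at 70.1 to 519 CPM in the other mutant-labelled embryos and at 94.4 to 185 CPM in wild type. Of 29 yolk sac endoderm genes 1 fell and 28 did not pass (adjusted p = 0.546). Wild-type embryo 1 had a yolk sac score (mean log2 CPM) of 4.08, against 5.21 to 5.65 in the other wild-type embryos and 4.07 to 6.03 in the mutant-labelled embryos, and with it and mutant-labelled embryo 2 left out 1 yolk sac gene fell and none rose (adjusted p = 0.216).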

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

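Of the tests in this part, those of the number of changed genes and lists under other splits and of near-identical copies, except for the 49 genes left aside below and the 3 genes with no copy, were set before their results were seen; the fit with the red cell score as a covariate was planned but its bound was set after its result was seen, and the others were chosen only after the result was seen. In 22 of 246 groups of embryos (8.94%), taken over list scores and genes chosen to be named, 1 embryo lay far from the rest. The 95% limit used gives about 1 in 20 by chance. Some of these genes, such as Hoxb9, were chosen after their values were seen. The groups also share embryos, so they are not independent, and 8.94% cannot be read against that rate.

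Mutant-labelled embryo 2 had the lowest posterior Hox scores, -1.03 for paralog groups 9 to 13 (mean log2 CPM; the other mutant-labelled embryos lay at 1.84 to 2.68) and 1.67 for groups 5 to 8 (3.28 to 3.6 in those embryos), with Hoxd13 at 0 CPM and Hoxb9 at 7.05 CPM, and its globin genes were lower than in any other embryo. Low depth is argued against by its total of 21346245 counts, the highest of the 12, and a wild-type embryo under a mutant label by its Tgif1 level of 6.86 CPM, far below the lowest wild-type embryo. Hox genes of groups 9 to 13 stood at a median log2 ratio of -3.13 to the other mutant-labelled embryos, and all 11 were lower by at least 2-fold. Presomitic and somite genes, a list that also holds genes of formed somites, stood at -0.08, with 9 of 32 lower by at least 2-fold. Presomitic genes picked after their values were seen lay below the range of the other mutant-labelled embryos. Msgn1 stood at 0 CPM (2.21 to 6.47 in those embryos), Tbx6 at 0.286 (3.14 to 8.19), Hes7 at 0.238 (2.35 to 6.29) and Dll3 at 0.762 (5.4 to 11.7). The list median therefore does not speak for presomitic genes alone. Over both lists the median was -0.78 (95% interval -2.32 to -0.03, 43 genes), which does not decide whether they fell together by 2-fold. Red cell genes stood at -2.18 (16 of 22 lower by 2-fold), yolk sac endoderm genes at -1.05 (16 of 29; its yolk sac score of 4.08 did not stand apart, with 4.07 in mutant-labelled embryo 8 and 4.08 in wild-type embryo 1), forebrain genes at 0 and heart genes at 0.46. Posterior tissue lost at dissection and an embryo truncated in life may each give the Hox values, and they cannot be told apart because whole-embryo counts hold no anatomy. No explanation of the low red cell genes was tested. The same embryo was also high in Ephx1 (4.57 CPM), Tnni1 (266 CPM) and, with 1 count, Rbm44 (0.0476 CPM).

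Genes at separate levels within a genotype formed a second pattern, with Rpl29 at 5.01 CPM and Ahcy at 7.29 CPM in wild-type embryo 2, near the level of the mutant-labelled embryos, and with others such as Hmgn2 and Kpna2 among the mutant-labelled embryos. Left aside here are Xist, Mira, for which no copies were searched, and 49 genes searched in which mutant-labelled embryo 2 (24 genes) or wild-type embryo 1 (25 genes) alone stood apart, a choice made after the levels of these embryos were seen and before copies were searched. Of the 10 other such genes 7 (70%) had a near-identical copy in the transcript set, against 9.59% of 12289 other genes (Fisher exact two-sided p = 7e-06, across genes). Of the 49 genes 2 had one (4.08%, 95% interval 0.498 to 14), which argues against copies as their cause. Over all 59 the share was 15.3%, against 9.61% of others (Fisher exact two-sided p = 0.178, across genes). Of the 10 genes 3, AA465934, Htra1 and Procr, had no copy, and the last 2 were high in mutant-labelled embryo 6 alone. Ctla2a, one of the 7 genes with a copy, was also high in that embryo alone, at 21.29 CPM. The other mutant-labelled embryos stood at 2.66 to 5.05 CPM, so this pattern arose with and without a copy. Reads shared between copies are thus a candidate explanation for the levels of the 7 genes with a copy, with that limit for Ctla2a. Among the transcripts searched they are not one for the levels of the 3 or of the 49 as a set. Copies outside that transcript set were not searched. Strain variants that segregate in the mixed background stay open for the 10 genes because gene counts hold no alleles, and for the 7 they cannot be told apart from shared reads. No biological explanation from the design was tested.

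The number of changed genes, 7423, was the third pattern. Of 100 splits of the 12 embryos into 4 and 8, 1, the real one, gave as many, which argues against chance. The highest other, 6 genes, came from the split that set the 4 embryos with Y-linked transcripts apart. The splits take the embryos as independent, which shared litters, not given by the labels, would break. GC content and transcript length, and blood content, are argued against as the whole cause. Of the changed genes, 87.1% still passed the threshold with the trends removed and 81.8% with the red cell score as a covariate. Direction was not compared in these counts. Near-identical copies are argued against as the whole cause of changes of at least 2-fold only, since 7.29% of those genes had one. A difference in stage, litter or batch cannot be told apart from genotype, since the labels give no litter or batch and the stage markers disagree: without mutant-labelled embryo 2, heart genes had a median log2 fold change of 0.64 and Hox genes of groups 9 to 13 one of -0.18. Genotype stays open with these. For the number of gene lists past the threshold, 12, chance is not excluded: 60 of 100 splits gave as many and the highest other gave 26.

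The remaining values that stood apart are given without explanation. Mutant-labelled embryo 6 was high in Hsd3b6 (6.06 CPM), Hand2 (99.6 CPM), Tie1 (84.1 CPM), the endothelial score (5.05) and the TGF-beta and Nodal score (5.06), and low in the RabGAP score (4.87). Mutant-labelled embryo 1 was high in Rpl3 (16.2 CPM) and embryo 3 in Axin2 (110 CPM). Wild-type embryo 1 was high in Nkx2-1 (3.36 CPM) and in the forebrain score (3.65). Wild-type embryo 4 was only slightly higher in Twsg1, at 139 CPM against about 136 CPM in the other wild-type embryos. It was low in Slc7a11, at 6.33 CPM against 7.95 to 8.23 CPM. The score of sex-linked genes was 3.73 in wild-type embryo 2, the wild-type embryo with Y-linked transcripts.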

How the results depend on the processing

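The GC and length correction and the omission of both embryos that stand apart were chosen after seeing the data. Over the scaling, test, filter, covariate and left-out settings the count of changed genes stayed within 1.5 times of 7423, and Tgif1 and Evi5l kept their direction and call. Leaving out 1 embryo gave 6485 to 7524 changed genes, 3369 to 3896 higher and 3107 to 3683 lower, log2 fold changes of -3.32 to -3.27 for Tgif1, 2.58 to 2.74 for Evi5l and 0.13 to 0.19 for Tgif2, and 10 to 12 lists. Tgif2 passed the threshold, upward, with sample quality weights (0.19, adjusted p = 0.0156) and without mutant-labelled embryo 8 (adjusted p = 0.0446), and lay near 0 with the red cell score as a covariate (0.01, adjusted p = 0.857) and with the GC and length trends removed (0.03, adjusted p = 0.714); the cause was not tested. Stricter demands on size lowered the counts by construction: 3223 genes (2079 higher, 1144 lower) against 1.2-fold, 2382 (1712 and 670) at 1.5-fold and 927 (726 and 201) at 2-fold. With the GC and length trends removed 42% of changed genes were higher, against 51.7%. The list count fell from 12 to 0 with an estimated correlation in camera (1 list at an unadjusted p under 0.05) and rose to 21 with fry, which does not compare a list with other genes. The red cell list lost its call with fry (adjusted p = 0.1). The counts that follow leave out fry and the estimated correlation, with which none of the 12 calls stood. Over these 25 alternatives the Wnt, endothelial, red cell and stress lists kept their calls in 17, 18, 21 and 23. The other 8 lists called kept theirs in all 25. The red cell list lost 1 of its calls by construction, to its own score as the covariate. Of 4257 alternative values for 159 other named genes, 4206 kept direction and call, 50 lost the call and 1 reversed, Xist at 0.02 with its own level as the covariate, which leaves nothing to test. Lists were not rerun for limma-voom, on which they already rest, or without robust dispersions, which they do not use.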

Other observations

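Imprinted genes rose more often than they fell in the mutant-labelled embryos. Of 25 tested, 14 rose and 4 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.00565, and 0.799 with an estimated correlation). Dlk1 rose from 242 ± 46.7 to 624 ± 55.9 CPM (SD, n = 4 and 8; log2 fold change 1.37, SE 0.11), Asb4 by 1.21 (SE 0.13) and Plagl1 by 1.2 (SE 0.14), each in 8 of 8 embryos. Cell cycle genes moved both ways. A list of cell cycle inhibitor and Myc genes also holds cyclin D, E2f and Gadd45 genes, so its counts do not speak for inhibitors alone. Of its 20 genes tested 9 rose and 6 fell. Ccnd3, which encodes cyclin D3 and has 1 near-identical copy, stood at 0.91 (SE 0.05), Cdkn1b at 0.65 (SE 0.07) and E2f1 at -0.39 (SE 0.06). Of 30 S and M phase genes 6 rose and 13 fell, with Kif23 at -0.56 (SE 0.05), Mcm4 at -0.41 (SE 0.03) and Birc5 at 0.56 (SE 0.05). Neither list passed as a set by camera (adjusted p = 0.425 and 0.259). Both passed by fry, which does not compare a list with other genes (adjusted p = 0.000142 and 0.00499).

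Death and neural crest genes also moved both ways. Of 28 p53 target and cell death genes 12 rose and 5 fell, with the death receptor gene Fas rising from 0.35 ± 0.126 to 2.12 ± 0.446 CPM (log2 fold change 2.58, SE 0.27) and Pmaip1, a pro-apoptotic p53 target, falling by 1.14 (SE 0.12). Of 30 neural crest genes 8 rose and 3 fell, with Ednrb at 1.09 (SE 0.11) and Snai2 at 0.91 (SE 0.11). Of 21 TALE homeobox and corepressor genes 8 rose and 4 fell, with Meis3, a relative of the targeted genes, at 1.09 (SE 0.07). The camera adjusted p of these lists was 0.333, 0.427 and 0.482. By fry it was 0.00499, 0.145 and 0.0686.

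Both hypotheses that follow were tested only after the result was seen. Loss of a repressor may leave more rises than falls among large changes, and at least 77.8% of genes changed by at least 2-fold rose under each of 3 scalings and 72.1% with the GC and length trends removed, where 42% of all changed genes rose, but indirect effects could give the same and the counts do not separate them. Variants linked to the targeted loci could change neighbours such as Dlgap1. Of 276 genes within 10 Mb of Tgif1 or Tgif2, 16 (5.8%) changed by at least 2-fold, against 6.43% of 14055 other genes (Fisher exact two-sided p = 0.804, across genes; odds ratio 0.895, 95% interval 0.502 to 1.49), so no excess was detected and an effect on single neighbours stays open.

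Xist stood at 275.15 CPM in mutant-labelled embryo 6 and at 426.66 to 540.89 CPM in the other mutant-labelled embryos without Y-linked transcripts.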
